A study of Glycine max and Glycine soja with 1003 samples.

How the data were processed

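The values were raw counts per gene, as the deposited table holds them: whole numbers for 56044 genes in 1003 library columns, with a different total in each column. By the submitters' processing notes, single-end reads were trimmed with Trimmomatic 0.36 and aligned with STAR 2.5.2b to a Glycine max genome, and STAR's own gene counts were collated. The notes were not checked against reads. The libraries came from a stranded mRNA kit, and the sources used here do not state which strand column was taken, so counts of overlapping or antisense genes are uncertain, as are counts of close paralogs. The table of normalised values was not used here.

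Photoperiod, temperature, genotype and sample time came from the sample labels, and the plate well came from the library title. Of the 1003 columns, 979 were used, and 24 without a plate well in the title were not used. When a plate well had 2 libraries, as in 75 wells, their counts were summed, giving 904 wells, of which 810 belonged to the 9 shared times. Repeat libraries of 1 well differed little more than counting error (median chi-square per degree of freedom 1.20), and the 2 wells of 1 combination differed more (17.4 over 405 combinations). A used library had as few as 2814 counts before summing. Counts made up 37.7 to 91.2% of the reads of a well, with a median of 89.1%, and 29 of the 810 wells lay under 80%. The labels do not say whether the 2 wells of a combination held different plants, so p-values measure only the spread between these samples. Values after ± are standard deviations over genotypes, times or conditions, or for fitted changes an approximate standard error, and none covers a plate difference.

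Gene counts between conditions came from edgeR quasi-likelihood F-tests on cell means, a cell being 1 combination of condition, genotype and time. Libraries were scaled by TMM, genes were filtered by filterByExpr, and the dispersion trend was taken from 600 genes, or from 5000 for sums per genotype. A contrast was the mean over genotypes and times of the log2 ratio, each with equal weight, and 14 such contrasts and 6 F-tests with several degrees of freedom were run, along with the comparison of genotype 5. All tests were two-sided, and p-values were adjusted over all tested genes by Benjamini and Hochberg's method at 0.05. Genotype 5 was compared on counts summed per genotype and condition. Where a gene had cells without counts on both sides of a contrast, the cell means could not be tested, and values are given from an additive edgeR fit of stratum, meaning genotype and time, plus condition. At 25 °C between SD and LD, 2657 genes were of that kind, and the additive fit called 1487 of them. Fitted changes of genes with cells at 0 depend on the prior count. The cell-means fit was computed by a purpose-written routine, which was compared with edgeR's own on 190 to 212 genes per contrast. At most 4 genes in a contrast differed by over 0.01 in log10 p, the largest difference among genes with counts in each cell was 3.82, and 0 calls changed.

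Gene sets were tested by limma's camera with a preset correlation of 0.01, and again with an estimated correlation. Of 54 set tests 6 passed with the preset value, and 1, the floral MADS-box genes between SD and LD at 16 °C, with the estimated correlation. The flowering list had 32 genes in 7 groups: 7 FT genes, 3 of the E1 family, 2 phytochrome A genes, 10 clock genes, 2 CONSTANS-like genes, 6 floral MADS-box genes and 2 Dt genes. The identifiers of these genes came from general knowledge of the soybean literature, not from the reference. Lists that rest on product names matched 0 of the 56044 identifiers and gave no result: FT/TFL1, MADS-box, CONSTANS-like, clock, photoreceptor, heat shock, cold and dehydration, light-harvesting, photosystem, Calvin cycle, flavonoid, histone, cell division and ribosomal genes.

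The samples, the tests, the flowering list, the rule for named genes and most alternatives were set before the data were examined. The rule named up to 8 flowering genes with the largest change per comparison, and the largest changes upward and downward among genes past the threshold with a mean of at least 1 log2 CPM and the same direction in all 5 genotypes. Up to 5 each way were planned, and at most 2 each way are given because the identifiers carried no product names. Not every flowering gene that the rule allows is given in each comparison, and other flowering genes named were chosen after their values were seen. The comparison of single genotypes in LD used a pseudocount of 0.1 CPM and exact sign permutations over the 9 times. The values at D0, with the same pseudocount, and the position of Sh used exact sign permutations over genotypes, 32 in number.

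The tests were also tried on simulated data, in which counts were drawn for real genes from their mean levels, the library sizes and the dispersion trend, and 200 genes were changed by known folds, up or down. For SD against LD at 25 °C, with 3932 genes, cell means recovered 73.5% of genes altered 1.2-fold, 98.0% at 1.5-fold, 98.0% at 2-fold and 92.0% at 4-fold, and 12 of 191 calls (6.28%) were false. The additive fit recovered 77.6% at 1.2-fold and 100% at the larger folds, with 11 of 198 false (5.56%). On the same genes limma-trend recovered 71.4%, 98.0%, 100% and 100%, with 12 of 195 false (6.15%), and with a replicate block 10 of 193 were false (5.18%). On sums per genotype, with 3969 genes, edgeR recovered 68.0%, 96.0%, 100% and 100%, with 7 of 187 false (3.74%), and DESeq2 68.0%, 94.0%, 100% and 100%, with 10 of 189 false (5.29%). For the photoperiod response at 16 against 25 °C, with 3934 genes, cell means recovered 60.0%, 94.0%, 94.0% and 91.8%, with 12 of 181 false (6.63%).

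For D7 against D1 in LD, with 3717 genes, recovery was 2.56%, 44.7%, 88.9% and 100%, with 9 of 121 false (7.44%), so small changes between single days were mostly missed. Variation over II1 to II6 in LD, with 3801 genes, was recovered in 0% of genes at 1.2-fold, 60.9% at 1.5-fold, 83.0% at 2-fold and 100% at 4-fold, with 7 of 123 false (5.69%), and by limma-trend in 0%, 58.7%, 80.9% and 100%, with 5 of 119 false (4.20%). The time pattern between SD and LD, with 3917 genes, gave 2.08%, 40.0%, 78.0% and 90.0%, with 3 of 108 false (2.78%). The response to photoperiod among genotypes, with 3932 genes, gave 0%, 46.0%, 82.0% and 93.9%, with 5 of 115 false (4.35%). Genotype 5, with 3999 genes, gave 98.0% at 1.2-fold and 100% at larger folds, with 13 of 212 false (6.13%), by DESeq2 98.0%, 98.0%, 100% and 100%, with 16 of 214 false (7.48%), and by limma-trend 96.0%, 98.0%, 100% and 100%, with 13 of 210 false (6.19%). False calls passed the nominal 5% in several of these settings. The simulated wells were independent, with no plate or chamber effect, and a far smaller share of genes changed than was called in the data. The false-call rates therefore do not cover such effects in the real contrasts.

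Alternatives covered the normalization (DESeq2 size factors), the test (limma-trend, and DESeq2 or edgeR with genotypes as replicates), the filter, the model, the wells, the genotypes, the sampling times, the library title prefix (in an additive limma-trend fit) and the correlation in set tests. Fits with 1 well per combination were additive. Added after the data were seen were the removal of wells that did not match their label, the removal of wells under 80% counted, limma-trend with a replicate block, the additive fit for genes that cell means could not test, and the spans of clustered genes without their end genes. Sample time D0, the I series and days D2, D4 and D6 were left out of the comparisons because they were not sampled in every condition or genotype. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.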

Results

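Gene expression was measured by RNA sequencing of soybean shoots harvested above the cotyledons, in 979 libraries from 5 genotypes coded 1 to 5. Genotypes 1 to 4 were lines of Glycine max, the cultivated soybean, and genotype 5 was a line of Glycine soja, its wild relative. Plants raised for 3 weeks at 25 °C under long days (LD, 14 h of light) or short days (SD, 10 h) were transferred to 16, 25 or 32 °C. The labels name a further photoperiod, Sh, without spelling it out. Each of the 9 combinations of photoperiod and temperature was sampled in all 5 genotypes on days D1, D3 and D7 and at 6 further times, II1 to II6, whose hours the labels do not state. These 9 shared times gave 405 combinations of condition, genotype and time, each with 2 plate wells, 810 wells in all. Wells held 5.73 to 46.7 M gene counts (M, 1e6), with a median of 14.9 M, and the median per condition ran from 11.3 M in SD at 16 °C to 24.3 M in Sh at 25 °C. At these times each plate held a single condition, so a plate or growth chamber cannot be told apart from the condition it carried. Levels are in CPM, counts scaled to library size, as the mean ± standard deviation of the 5 genotypes unless stated otherwise. Changes are log2 ratios averaged over genotypes and times, ± an approximate standard error. Such an average weights times of low expression as heavily as the peak, so for genes with a wide swing over time, among them E2 and the LHY genes, it can differ in size or direction from the change of the mean level.

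The first question was which genes respond to day length at 25 °C. Florigen genes, whose products move from leaf to shoot tip and promote flowering, were far higher in SD: FT2a (Glyma.16G150700) stood at 38.1 ± 6.75 CPM in SD and 4.01 ± 4.77 CPM in LD (n = 5), and FT5a (Glyma.16G044100) at 38.9 ± 5.48 and 7.05 ± 7.54 CPM. Their log2 changes were 5.08 ± 0.11 and 3.43 ± 0.08, and FT2b (Glyma.16G151000) rose by 8.49 ± 0.20 from 0.0376 ± 0.0739 CPM in LD. The FT homologs that repress flowering went the other way: FT1a (Glyma.18G298900) fell by 7.13 ± 0.34 on the log2 scale, from 2.44 ± 2.02 to 0.00580 ± 0.00759 CPM, and FT4 (Glyma.08G363100) fell by 5.23 ± 0.26. E1 (Glyma.06G207800), the legume-specific repressor of florigen genes, was at 0.709 ± 0.227 CPM in LD and 0.0320 ± 0.0174 CPM in SD. All 5 genotypes shared the direction of each of these 6 genes. For genes with cells without counts, among them FT1a in SD and FT2b in LD, the size of a change depends on the prior count. The value after ± does not cover this, here and below.

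Among the 7 FT genes, 5 could be tested at 25 °C, and 3 rose in SD while 2 fell. Of the 6 floral MADS-box genes, 4 rose, 1 fell and 1 did not pass. The rising members were the homologs of APETALA1, a floral meristem identity gene: AP1a (Glyma.16G091300) by 5.04 ± 0.23, AP1b (Glyma.01G064200) by 5.67 ± 0.22, AP1c (Glyma.02G121600) by 3.94 ± 0.16 and AP1d (Glyma.08G269800) by 2.58 ± 0.14. SOC1b (Glyma.09G266200), a homolog of the floral integrator SOC1, fell by 0.17 ± 0.04. Of the 10 clock genes, 3 rose and 5 fell in the average over times. PRR3b (Glyma.12G073900), a pseudo-response regulator, fell by 0.35 ± 0.03, and J (Glyma.04G050200), the ELF3 homolog, rose by 0.19 ± 0.04. The change of -0.10 ± 0.04 for the GIGANTEA homolog E2 (Glyma.10G221500) averages log ratios over times at which it was nearly silent, and its mean level was 201 ± 42.7 CPM in SD and 154 ± 33.2 CPM in LD. An additive fit of stratum and condition gave 0.04 for E2, with an adjusted p of 0.787. E4 (Glyma.20G090000), a phytochrome A gene, rose by 0.20 ± 0.03, and E3 (Glyma.19G224200), the other one listed, did not pass with 0.01 ± 0.03. Members of the E1 family had wells without counts on both sides and could not be tested by cell means. In the additive fit E1 changed by -4.08 ± 0.19, E1La (Glyma.04G156400) by -5.74 ± 0.19 and E1Lb (Glyma.04G143300) by -4.67 ± 0.19.

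Across all genes, 28181 of 41365 tested differed between SD and LD at 25 °C, 14000 up and 14181 down in SD (edgeR, adjusted p under 0.05). At least 2-fold changes were rarer, with 584 genes up and 857 down. Of the 32 flowering genes, fixed as a list before the data were examined, 26 could be tested and 21 passed (12 up, 9 down), also 21 when adjusted over the list alone. The floral MADS-box genes rose as a set (camera, adjusted p = 3.80e-04), a call lost with an adjusted p = 0.155 with an estimated correlation. Outside the flowering list, the largest change upward by the naming rule was that of Glyma.04G159300 (5.07 ± 0.10), and the largest downward were those of Glyma.06G312600 (-6.48 ± 0.38) and Glyma.11G063400 (-5.53 ± 0.27). The p-values measure the spread between wells, and with 180 wells per comparison small differences pass.

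**Figure D1:**
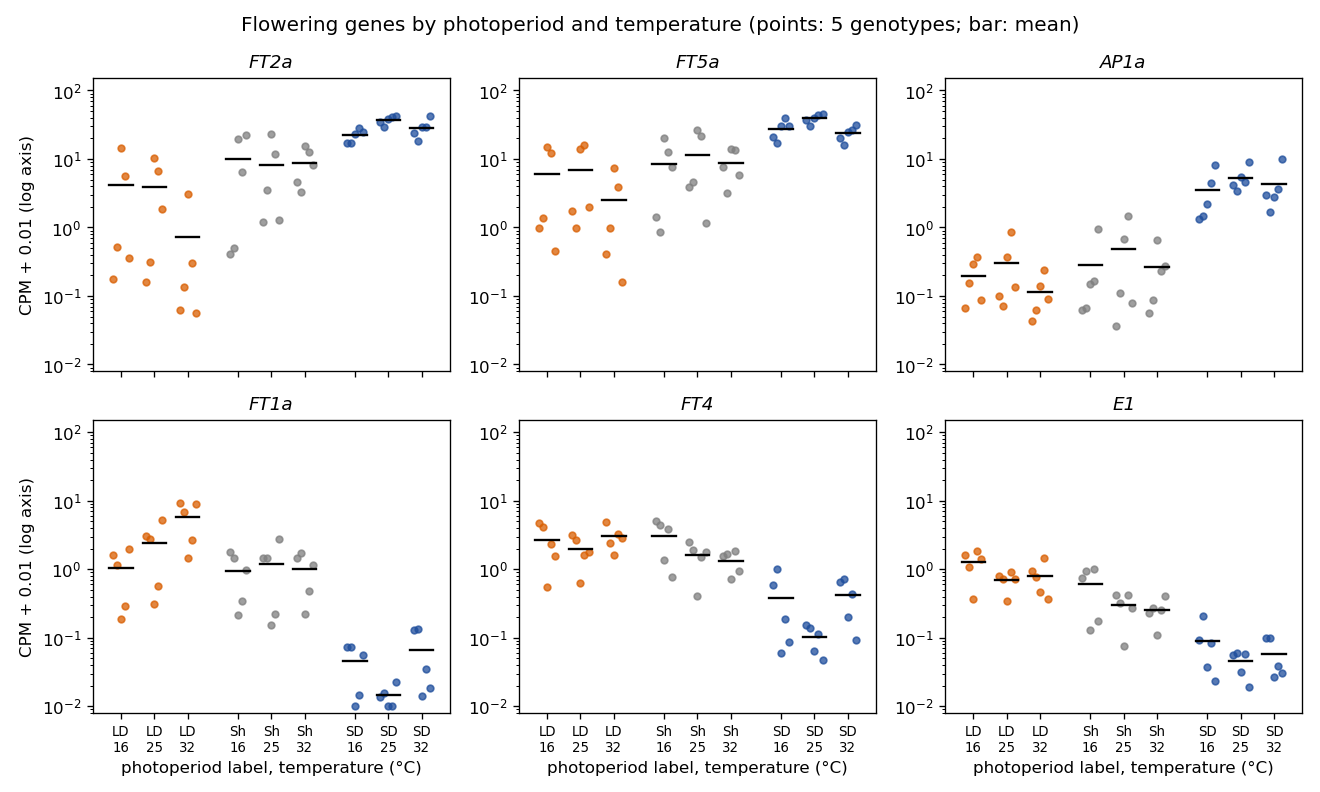
Levels of FT2a, FT5a, AP1a, FT1a, FT4 and E1 in CPM (log axis, 0.01 added) under LD, Sh and SD at 16, 25 and 32 °C, with 1 point per genotype and a bar at the mean of the 5 genotypes. FT2a and FT5a lie highest in SD, at 38.1 and 38.9 CPM at 25 °C, and FT1a, FT4 and E1 lie lowest there.

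The same contrast was drawn at 16 and 32 °C to ask whether the response to day length persists away from the raising temperature. FT2a rose in SD by 4.65 ± 0.13 at 16 °C and by 7.34 ± 0.15 at 32 °C. Its level in LD was 3.80 ± 5.50 CPM at 16 °C and 0.777 ± 1.31 CPM at 32 °C, against 22.9 ± 5.16 and 29.4 ± 8.68 CPM in SD. FT5a rose by 3.49 ± 0.10 and 4.64 ± 0.11, and at 32 °C FT2b rose by 8.09 ± 0.44. FT1a fell by 4.91 ± 0.43 at 16 °C and by 7.41 ± 0.27 at 32 °C, and FT4 fell by 3.38 ± 0.18 and by 3.90 ± 0.17. E1 was at 1.24 ± 0.539 CPM in LD and 0.0761 ± 0.0690 CPM in SD at 16 °C, and at 0.808 ± 0.450 and 0.0447 ± 0.0351 CPM at 32 °C. In the additive fit E1 fell by 3.67 ± 0.19 at 16 °C and by 3.75 ± 0.24 at 32 °C.

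At 16 °C all 6 floral MADS-box genes rose in SD, and AP1a rose by 4.71 ± 0.20. The SOC1 homologs SOC1a (Glyma.18G224500) and SOC1b joined them with 0.32 ± 0.04 and 0.23 ± 0.04. At 32 °C the 4 AP1 homologs rose and neither SOC1 gene passed, with 0.05 ± 0.03 for SOC1a and 0.02 ± 0.04 for SOC1b. Dt2 (Glyma.18G273600), a MADS-box gene known for its effect on stem growth habit, rose by 0.83 ± 0.07 at 16 °C and by 1.72 ± 0.13 at 32 °C. Among the clock genes, J rose by 0.20 ± 0.04 at 16 °C and fell by 0.44 ± 0.05 at 32 °C, where LUX2 (Glyma.11G136600), an evening clock gene, fell by 0.68 ± 0.08.

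The counts were 21964 of 40579 genes at 16 °C (10613 up, 11351 down) and 29718 of 41666 at 32 °C (14970 up, 14748 down). At least 2-fold changes numbered 167 up and 545 down at 16 °C, and 1476 up and 1550 down at 32 °C. Of the flowering genes, 21 of 25 passed at 16 °C (16 up, 5 down) and 22 adjusted over the list alone, and 17 of 26 at 32 °C (10 up, 7 down), also 17 adjusted over the list alone. The rise of the floral MADS-box genes as a set was called at 16 °C (adjusted p = 3.86e-10) and held there (adjusted p = 0.00225 with an estimated correlation). At 32 °C it was lost, with an adjusted p = 0.155 with an estimated correlation. The flowering genes as a whole were called upward at 16 °C (adjusted p = 0.0161), a call lost with an adjusted p = 0.262 with an estimated correlation. With the 5 genotypes as replicates, edgeR called 3593 genes at 16 °C and DESeq2 7191, with D1, D3 and D7 alone the count was 11555, and in additive fits with 1 well per combination it was 10358 to 10967. At 32 °C the number of flowering genes past the threshold was 26 on those 3 days alone.

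The libraries at 16 and 32 °C are separate, so their responses to day length could be compared across genes. Among 40098 genes tested in both, 77 rose at least 2-fold in SD at both temperatures, where independent lists would share 5.96, and 45 fell at both, where 18.9 would be shared. Another 104 genes passed 2-fold in opposite directions, and the number that independent lists would give for these was not computed. The shared genes alone therefore do not show a common response. Over genes the Pearson correlation of the log2 changes was 0.157 and the Spearman correlation -0.00308, and genes are not independent replicates.

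Whether temperature altered the day-length response was tested directly. FT5a responded more strongly at 32 °C than at 25 °C, by 1.23 ± 0.16 on the log2 scale, and so did Dt2, by 1.25 ± 0.14. FT2a could not be tested by cell means, and the additive fit put its difference at 1.97 ± 0.29 (adjusted p = 1.30e-10). The evening clock genes J (-0.62 ± 0.06), LUX1 (Glyma.12G060200, -0.66 ± 0.15) and LUX2 (-0.74 ± 0.10) responded to SD less positively at 32 °C than at 25 °C. Between 16 and 25 °C, no difference passed for FT5a, with 0.06 ± 0.13. The largest differences among tested flowering genes at 16 °C were those of COL1a (Glyma.08G255200), a CONSTANS-like gene, with 0.53 ± 0.07, LHY2b (Glyma.03G261800), a morning clock gene, with 0.52 ± 0.09, and PRR3b with 0.47 ± 0.05. In the additive fit COL1a (adjusted p = 0.00798) and PRR3b (adjusted p = 0.0343) passed and LHY2b did not (adjusted p = 0.0505), and of the 10 clock genes 1 passed, against 6 by cell means. The mean level of PRR3b was nearly alike in SD and LD, with 193 and 199 CPM at 25 °C and 133 CPM in both at 16 °C.

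The response differed from that at 25 °C in 24009 of 41770 genes at 16 °C (12281 more positive, 11728 more negative) and in 30006 of 42390 genes at 32 °C (15698 and 14308). In additive fits with 1 well per combination the count at 16 °C was 14362 to 15145. By at least 2-fold it differed in 444 and 1251 genes at 16 °C, and in 3193 and 2707 genes at 32 °C. Of 19 flowering genes testable at each temperature, 12 passed at 16 °C (10 more positive, 2 more negative) and 13 at 32 °C (8 and 5), with the same 12 and 13 adjusted over the list alone. The limma-trend test, which also tests genes with cells without counts, passed 23 and 20 flowering genes.

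Sh at 25 °C was compared with both defined day lengths. FT2a in Sh stood at 8.27 ± 9.71 CPM, which was 1.91 ± 0.15 above LD on the log2 scale, and against SD it fell by 3.19 ± 0.07. FT5a rose against LD by 0.86 ± 0.10 and fell by 2.57 ± 0.07 against SD. FT1a fell by 1.09 ± 0.11 against LD and rose by 6.38 ± 0.27 against SD, FT4 rose by 5.18 ± 0.17 against SD and FT2b fell by 8.27 ± 0.17. The AP1 homologs stayed low in Sh, with AP1a at 0.482 ± 0.658 CPM, and AP1a fell by 4.85 ± 0.25 against SD. E1 was at 0.294 ± 0.138 CPM in Sh, and in the additive fit it changed by -1.09 ± 0.17 against LD and by 2.98 ± 0.21 against SD.

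Both CONSTANS-like genes were higher in Sh than in either day length. COL1a rose by 0.74 ± 0.05 against LD and by 0.94 ± 0.04 against SD, and COL1b (Glyma.18G278100) by 0.77 ± 0.05 and 0.83 ± 0.05, at a level of 177 ± 16.4 CPM in Sh. LUX2 rose by 0.77 ± 0.06 against LD and by 0.69 ± 0.05 against SD. Of the 10 clock genes, 5 rose and 4 fell against LD. Outside the flowering list and by the naming rule, Glyma.19G187300 (3.35 ± 0.17) and Glyma.05G084400 (3.23 ± 0.16) rose most against LD, and Glyma.15G062700 (-3.81 ± 0.20) fell most. Against SD, Glyma.16G200700 (-4.08 ± 0.07) fell most within the same limits.

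Sh and LD differed in 27392 of 41435 genes (13102 up, 14290 down), with 556 up and 623 down at least 2-fold, a sum of 1179 that became 1830 with II1 to II6 alone. Sh and SD differed in 29219 of 42022 genes (15739 up, 13480 down), with 789 up and 1279 down at least 2-fold, and edgeR with genotypes as replicates called 19394. Of the flowering genes, 17 of 22 passed against LD (11 up, 6 down) and 16 adjusted over the list alone. Against SD 25 of 26 passed (13 up, 12 down), also 25 adjusted over the list alone. The fall of the floral MADS-box genes against SD (adjusted p = 3.40e-04) was lost with an adjusted p = 0.0785 with an estimated correlation.

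Where Sh lay between LD and SD was measured on genes chosen from other libraries, the 77 that rose and the 45 that fell at least 2-fold in SD at both 16 and 32 °C. On a scale from 0 at LD to 1 at SD, Sh lay at 0.335 ± 0.137 (standard deviation, n = 5 genotypes), from 0.129 in genotype 5 to 0.473 in genotype 3. Both differences, from LD and from SD, had a two-sided exact sign permutation p of 0.0625, the smallest that 5 genotypes allow. The position rested on which genes were used: genes with at least 4-fold change gave 0.205, the rising genes alone 0.150, the falling genes alone 1.36 (exact p of 0.938 against SD), and genes chosen without a fold limit -3.39, where LD and SD scored nearly alike.

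Heat was examined within LD, where 32 °C was compared with 25 °C. Florigen genes were lower in the heat: FT5a fell by 1.91 ± 0.15, from 7.05 ± 7.54 to 2.64 ± 3.14 CPM, and FT2a, at 0.777 ± 1.31 CPM, fell by 2.85 ± 0.25 in the additive fit. The repressors FT1a and FT4 rose by 1.64 ± 0.11 and 0.71 ± 0.11, and FT1a reached 5.92 ± 3.68 CPM. No change passed in the additive fit for E1 (0.21 ± 0.22, adjusted p = 0.369). J rose by 0.85 ± 0.05 and Dt2 fell by 1.52 ± 0.13. Clock genes were split, with J, LUX2 (0.64 ± 0.08) and PRR3a (Glyma.U034500, 0.42 ± 0.05) up, and LHY1a (Glyma.16G017400, -0.34 ± 0.05), a morning clock gene, down in the averaged log ratio. The mean level of LHY1a went the other way, from 1053 ± 43.5 to 1222 ± 113 CPM.

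Cold gave another picture in LD. The averaged log ratio of E2 was 1.07 ± 0.05 at 16 °C, where its lowest point was 26.0 ± 7.39 CPM against 1.49 ± 0.628 CPM at 25 °C, and its mean level went from 154 ± 33.2 to 169 ± 13.9 CPM. LUX1 rose by 0.95 ± 0.09, while LHY1b (Glyma.07G048500) fell by 0.66 ± 0.05. The phytochrome A genes E3 and E4 fell by 0.51 ± 0.03 and by 0.40 ± 0.03. AP1d fell by 1.46 ± 0.26 and FT1a by 1.05 ± 0.13, and in the additive fit E1 rose by 0.84 ± 0.17, E1La by 0.64 ± 0.17 and E1Lb by 1.08 ± 0.17. COL1a and COL1b rose by 0.59 ± 0.05 and 0.78 ± 0.05.

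Heat changed 32422 of 41502 genes in LD (16077 up, 16345 down), 2982 up and 2972 down by at least 2-fold. Wells of LD at 32 °C included the lowest share of reads counted, 37.7%. The poorest agreement between the 2 wells of a combination also lay there, in genotype 5. The highest chi-square per degree of freedom was 112, at D3, and the lowest Pearson r was 0.754, at II3. The same wells enter SD against LD at 32 °C and the test of its difference from the raising temperature. All these counts stayed within 1.5 times when wells under 80% counted, or wells not matching their label, were removed. Cold changed 26190 of 40806 (13760 up, 12430 down), 373 up and 360 down by at least 2-fold. By the naming rule, the largest rises in the heat were those of Glyma.09G185500 (7.25 ± 0.35) and Glyma.01G204800 (7.13 ± 0.27). The largest falls by that rule were those of Glyma.06G312600 (-7.42 ± 0.31) and Glyma.11G063400 (-6.07 ± 0.29). In the cold, Glyma.05G147000 (2.74 ± 0.31) rose most and Glyma.13G075900 (-2.30 ± 0.16) fell most by the same rule. Flowering genes past the threshold numbered 13 of 21 in the heat (6 up, 7 down) and 20 of 21 in the cold (10 and 10), with the same counts adjusted over the list alone. The count of 13 became 21 by limma-trend and 20 with II1 to II6 alone. With genotypes as replicates, edgeR called 16581 genes in the cold, and with D1, D3 and D7 alone the count was 17053.

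Within SD the florigen genes fell on both sides of 25 °C. At 32 °C FT2a fell by 0.47 ± 0.07, FT5a by 0.72 ± 0.06 and FT2b by 1.07 ± 0.12. At 16 °C FT2a fell by 0.80 ± 0.07, from 38.1 ± 6.75 to 22.9 ± 5.16 CPM, FT5a fell by 0.42 ± 0.06 and FT2b fell by 3.66 ± 0.13, from 6.99 ± 2.25 to 1.00 ± 0.716 CPM. All 4 AP1 homologs fell at 16 °C, AP1d by 1.16 ± 0.12, whereas AP1a (-0.48 ± 0.10) and AP1b (-0.46 ± 0.10) fell at 32 °C and AP1c and AP1d did not pass. SOC1a and SOC1b rose in the cold by 0.42 ± 0.03 and 0.49 ± 0.04. COL1a rose by 1.10 ± 0.04 and COL1b by 1.07 ± 0.05 at 16 °C, and E3 fell by 0.77 ± 0.03. The averaged log ratio of E2 was 1.37 ± 0.04 and turned to -0.0483 on D1, D3 and D7 alone. Its mean level did not rise, with 201 ± 42.7 CPM at 25 °C and 195 ± 39.7 CPM at 16 °C, and its lowest point was 1.13 ± 0.221 CPM at 25 °C and 29.8 ± 5.08 CPM at 16 °C.

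Heat changed 28036 of 41510 genes in SD (14075 up, 13961 down), 384 up and 555 down by at least 2-fold. Cold changed 30595 of 41160 (14673 up, 15922 down), 886 up and 1848 down by at least 2-fold. Of the flowering genes, 19 of 24 passed in the heat (6 up, 13 down) and 23 of 24 in the cold (12 up, 11 down), with the same counts adjusted over the list alone. By the naming rule, Glyma.14G214800 (2.65 ± 0.14) rose most in the heat and Glyma.13G048800 (-2.67 ± 0.10) fell most. Under the same rule, Glyma.06G312600 (5.71 ± 1.94) rose most in the cold. The responses of LD and SD plants come from separate libraries. For the heat, 98 genes rose and 187 fell at least 2-fold in both, where independence would give 27.3 and 39.1, and 102 went opposite ways. For the cold, 107 rose and 204 fell in both, against 8.13 and 15.5, and 38 went opposite ways. No number under independence was computed for the opposite changes in heat or cold. The Pearson correlation across genes, which are not independent replicates, was 0.185 for the heat and 0.477 for the cold.

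Times II1 to II6 showed how genes varied over a series of harvests. All 10 clock genes varied over these times in LD and in SD at 25 °C, and so did both CONSTANS-like genes and both phytochrome A genes. LHY1a peaked at II1 with 2475 ± 106 CPM in LD and was lowest at II4 with 46.2 ± 5.10 CPM. PRR3b peaked at II3 in LD (389 ± 44.4 CPM) and in SD (331 ± 17.5 CPM), and E2 at II3 with 277 ± 54.6 and 380 ± 49.9 CPM. LUX2 peaked at II4 with 20.8 ± 2.15 CPM in LD and 40.6 ± 5.61 CPM in SD. J peaked at II5 in LD (111 ± 30.4 CPM) and at II4 in SD (178 ± 37.0 CPM). E1 peaked at II4 in LD with 2.57 ± 0.726 CPM, and its lowest mean was 0.0820 ± 0.131 CPM at II6. FT5a in SD ran from 56.5 ± 13.8 CPM at II1 to 17.8 ± 5.02 CPM at II4.

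The swing of LHY1a in LD was smaller at 16 °C and larger at 32 °C than at 25 °C, and the size of swings was not tested. At 16 °C in LD the peak of LHY1a was 1085 ± 161 CPM and its lowest point 113 ± 26.4 CPM, and at 32 °C they were 4001 ± 737 and 16.9 ± 3.14 CPM. COL1b peaked at II1 at 25 and 32 °C and at II6 at 16 °C, in LD (335 ± 110 CPM) and in SD (703 ± 306 CPM). E1 peaked at II5 at 16 °C (3.44 ± 1.98 CPM) and at 32 °C (1.62 ± 1.76 CPM). All 10 clock genes passed the test of a different time pattern at 16 °C and at 32 °C in LD.

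Over II1 to II6, 30681 of 39780 genes varied in LD and 34985 of 40648 in SD at 25 °C. The pattern differed between SD and LD in 18150 of 41123 genes, between 16 and 25 °C in LD in 23976 of 40416, and between 32 and 25 °C in LD in 24856 of 41203. Flowering genes past these 5 tests numbered 24 of 29, 23 of 26, 19 of 32, 21 of 30 and 22 of 30, and 25, 23, 20, 21 and 22 adjusted over the list alone. The test between SD and LD passed the 10 clock genes and none of the 3 E1 family members, all 3 of which passed in limma-trend with an adjusted p of 2.02e-14 for E1. Since the hours are not stated, times were treated as unordered.

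**Figure D2:**
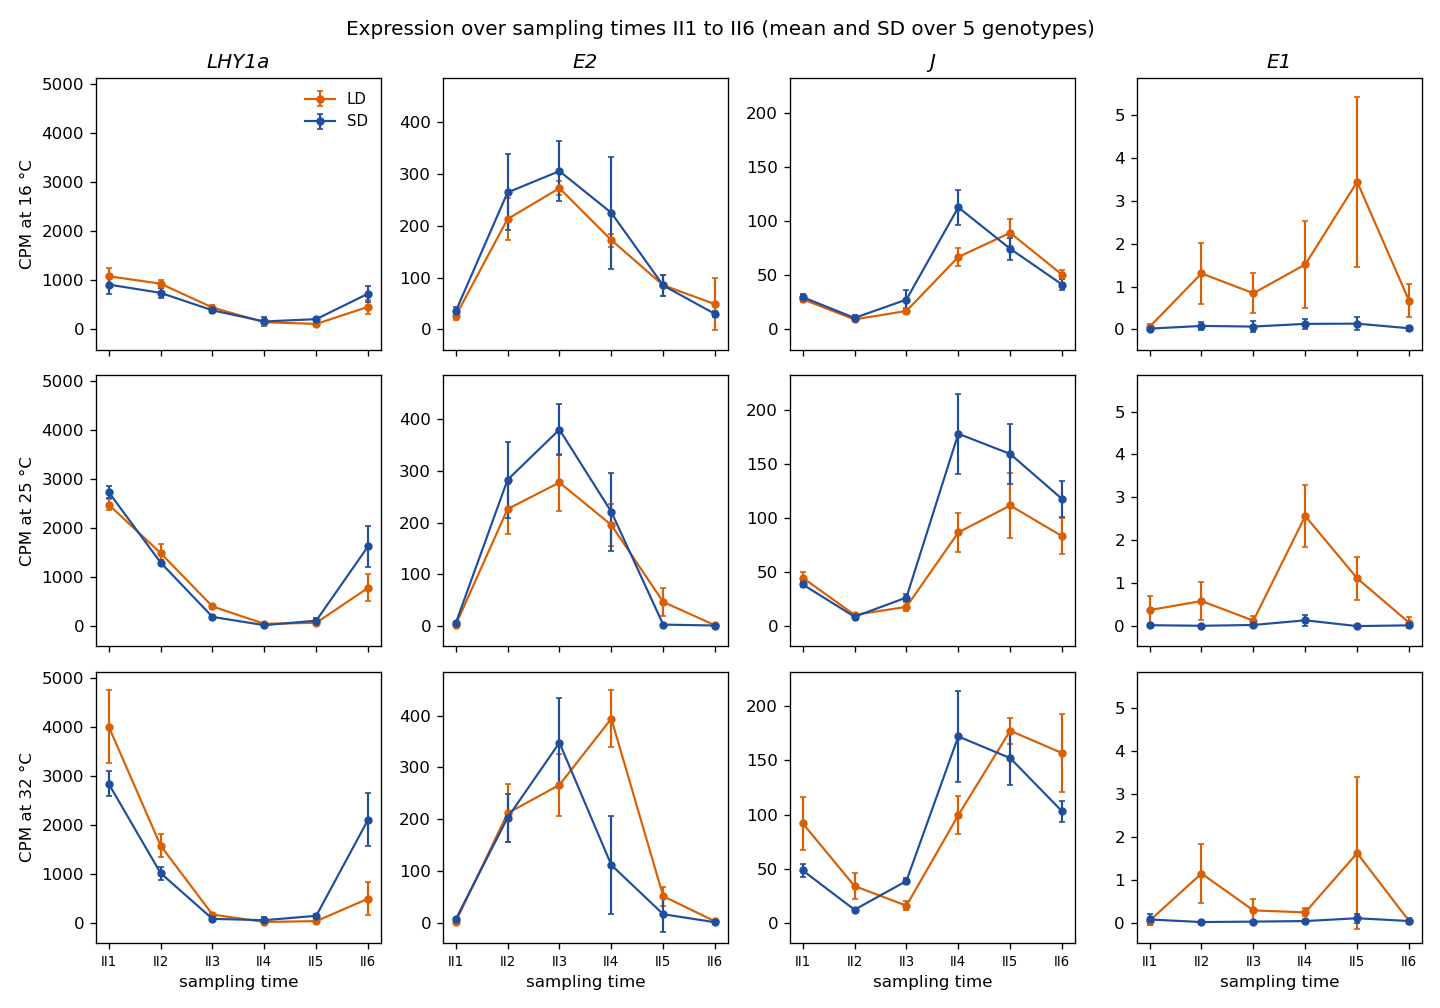
Mean level of LHY1a, E2, J and E1 in CPM (vertical axis) over the times II1 to II6 in LD and SD at 16, 25 and 32 °C, with error bars of 1 standard deviation over the 5 genotypes. LHY1a is highest at II1, at 1085 CPM in LD at 16 °C and 4001 CPM at 32 °C, and E1 stays near 0 in SD.

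The days after transfer were compared within 25 °C, between D7 and D1. In LD FT2a rose by 3.41 ± 1.14 and FT5a by 2.51 ± 0.19 over this span, and Dt2 rose by 1.13 ± 0.19. In SD FT2a rose by 0.66 ± 0.15 and FT2b by 1.11 ± 0.17, and all 4 AP1 homologs rose, AP1a by 2.23 ± 0.34 and AP1b by 1.83 ± 0.37. FT5a did not pass in SD, with 0.06 ± 0.13, and its change differed between SD and LD by -2.46 ± 0.25. COL1a and COL1b fell in SD by 0.75 ± 0.11 and by 0.67 ± 0.11, and in LD COL1b rose by 0.51 ± 0.08. The difference for COL1b was -1.20 ± 0.14. That for E1 was -3.31 ± 1.06, but E1 was too low in SD to be tested there, and its change in LD did not pass (0.91 ± 0.38). The call for FT5a ended in an additive fit (adjusted p = 0.0907), and in an additive limma-trend fit with the library title prefix as a term 0 flowering genes passed the test of the difference, where limma-trend on cell means passed 18.

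From D1 to D7, 13256 of 37902 genes changed in LD (6415 up, 6841 down) and 9934 of 38883 in SD (4984 up, 4950 down). The change differed between SD and LD in 10775 of 39336 genes (5459 more positive, 5316 more negative). At least 2-fold, the numbers were 1411 up and 913 down in LD, 792 and 733 in SD, and 1188 and 1915 for the difference. Flowering genes past the threshold were 12 of 25 in LD (9 up, 3 down), 10 of 24 in SD (7 up, 3 down) and 11 of 23 for the difference (2 and 9), and 14, 10 and 13 adjusted over the list alone. As a set they were called upward in LD (adjusted p = 0.00952), a call lost with an adjusted p = 0.262 with an estimated correlation. These counts were less firm than those over 9 times: in additive fits with 1 well per combination they ran from 2448 to 3817 in LD, from 471 to 807 in SD and from 581 to 3339 for the difference, and in an additive limma-trend fit with the library title prefix as a term the difference gave 1307, against 11066 by limma-trend on cell means. With genotype 2 left out the flowering count in LD was 7, and with genotype 1 left out 6391 genes changed in SD.

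The 5 genotypes did not respond to day length alike. FT2a and FT5a in LD separated them: at 25 °C FT2a averaged 0.156 ± 0.105 and 0.366 ± 0.442 CPM in genotypes 1 and 2 (standard deviation over 9 times), 11.3 ± 5.03 and 6.35 ± 3.47 CPM in genotypes 3 and 4, and 1.88 ± 1.37 CPM in genotype 5. FT5a averaged 1.80 ± 1.24 and 0.984 ± 0.455 CPM in genotypes 1 and 2, and 14.6 ± 5.22 and 15.9 ± 6.82 CPM in genotypes 3 and 4. In SD at 25 °C FT2a lay between 28.2 ± 6.86 CPM in genotype 2 and 45.7 ± 21.1 CPM in genotype 5. FT1a, a flowering repressor, was lower in LD in genotypes 3 (0.322 ± 0.202 CPM) and 4 (0.550 ± 0.217 CPM) than in genotypes 1 (3.46 ± 2.31 CPM), 2 (2.79 ± 1.54 CPM) and 5 (5.10 ± 2.65 CPM).

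Against the mean of genotypes 1 and 2 in LD at 25 °C, FT2a was higher by 5.02 ± 0.85 in genotype 3 and by 4.11 ± 0.78 in genotype 4 on the log2 scale (± standard deviation over 9 times), in 9 of 9 times in each. The values were 5.02 ± 1.26 and 3.46 ± 1.39 at 16 °C, and 3.99 ± 0.75 and 0.96 ± 1.57 at 32 °C, also in 9 of 9 times in each. The two-sided exact sign permutation p was 0.00391, the smallest that 9 times allow, and 0.0119 after adjustment over 156 such tests. The 9 times are serial harvests of the same lines, so such a p measures agreement over times and not replication of a genotype difference. Wells nearest to another genotype than labelled were kept in all tests of this kind, which were not repeated without them. In LD at 32 °C they included a well of genotype 4 at D1 and a well of genotype 2 at D7, and at 16 °C a well of genotype 2 at II1. FT2a in genotype 4 at 32 °C stood at 3.92 CPM on D1, against 0.173 CPM on D3 and 0.212 CPM on D7. The E1 family was compared in the same way. In genotype 3, E1 (-1.01 ± 0.59), E1La (-1.43 ± 0.81) and E1Lb (-1.39 ± 0.61) were lower in 9 of 9 times, each with an exact p of 0.00391. In genotype 4, E1 stood at 0.26 ± 0.58, higher in 6 of 9 times, with an exact p of 0.223. In genotype 3 all 3 were also lower in LD at 16 °C (adjusted exact p of 0.0222 for E1 and 0.0119 for E1La and E1Lb), and at 32 °C none passed (adjusted exact p of 0.197 for E1, 0.0569 for E1La and 0.0771 for E1Lb). In genotype 4 none passed at 25 °C, E1La and E1Lb were higher at 16 °C (adjusted exact p of 0.0119 and 0.0358) and at 32 °C (adjusted exact p of 0.0119 for both), and E1 did not pass at 16 °C (adjusted exact p of 0.929) or at 32 °C (adjusted exact p of 0.0569). Genotypes 3 and 4 were not tested against each other. E3 was lower in genotype 3 in 9 of 9 times, with -1.05 ± 0.22. These contrasts between single genotypes were chosen after the data were seen.

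The response to SD differed among genotypes in 7184 of 41365 genes, and in 7762 by limma-trend. FT2a (adjusted p = 2.14e-30) and FT5a (adjusted p = 7.63e-33) were among the 10 flowering genes of 32 that passed, with 11 adjusted over the list alone and 20 by limma-trend. Of the clock genes 1 passed, J (adjusted p = 0.0419). Both CONSTANS-like genes and 4 of the 6 floral MADS-box genes passed. Without genotype 3 the number of genes was 2928 and without genotype 5 it was 2858.

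**Figure D3:**
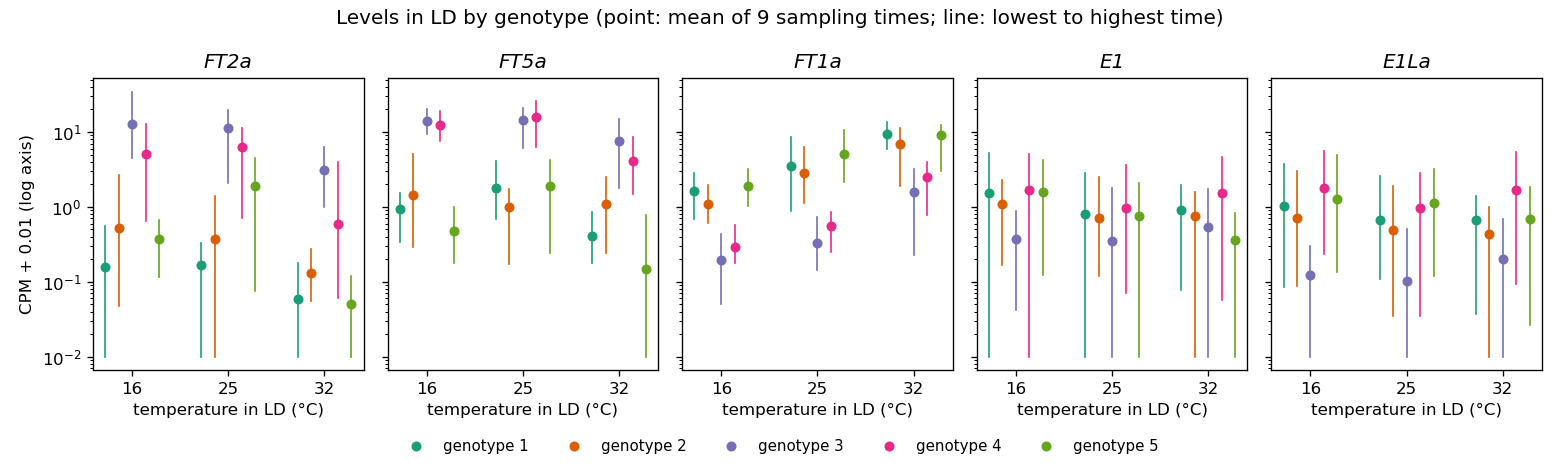
Levels of FT2a, FT5a, FT1a, E1 and E1La in CPM (log axis, 0.01 added) in LD at 16, 25 and 32 °C, with a point at the mean of 9 times for each of genotypes 1 to 5 and a line from the lowest to the highest time. Genotypes 3 and 4 lie above genotypes 1 and 2 in FT2a (11.3 and 6.35 against 0.156 and 0.366 CPM at 25 °C).

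The last comparison set genotype 5, the 1 line of Glycine soja, against the mean of genotypes 1 to 4 over the 9 conditions. A difference is one of this line and cannot stand for the species. The test used counts summed per genotype and condition. Its p-values and standard errors thus measure the spread over conditions, not over wells or plants. FT1a was higher by 1.50 ± 0.17 on the log2 scale, in 8 of 9 conditions, and FT1b (Glyma.18G299000) by 3.51 ± 0.31, in 8 of 9. SOC1a fell by 0.45 ± 0.04 relative to the other lines and was lower in 9 of 9 conditions, and LUX1 fell by 0.56 ± 0.09, lower in 8 of 9. The 4 AP1 homologs were higher, AP1b by 1.37 ± 0.39 in 7 of 9 conditions and AP1c by 1.27 ± 0.29 in 5 of 9. Among other FT genes the largest difference was that of FT3a (Glyma.16G044200), higher by 4.76 ± 0.31 though in 5 of 9 conditions, at 0.316 ± 0.520 CPM in genotype 5 and at most 0.0255 ± 0.0493 CPM in genotypes 1 to 4. FT2b was higher by 1.40 ± 0.45, in 5 of 9 conditions, a call that ended by limma-trend (adjusted p = 0.135) and by DESeq2 (adjusted p = 0.0811). FT2a and FT5a did not pass, with 0.13 ± 0.48 and -0.63 ± 0.38.

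In all, 32935 of 44739 genes differed in genotype 5, 16978 higher and 15957 lower, with 2665 higher and 3014 lower by at least 2-fold. Of the 32 flowering genes 11 were higher, 8 lower and 13 did not pass, and 19 also passed adjusted over the list alone. Among genes with a mean of at least 1 log2 CPM and the same direction in 9 of 9 conditions, Glyma.04G180400 (9.52 ± 0.77) was highest. Glyma.14G168800 (-7.55 ± 0.34) was lowest among them. Against genotype 1 alone FT1a turned to -0.0365, against genotype 3 alone FT2b to -0.86 and against genotype 4 alone AP1a to -0.20, and against genotype 2 alone 21953 genes and 8 flowering genes passed. Reads of genotype 5 were counted on the annotation of a Glycine max genome, so a sequence difference and an expression difference cannot be separated for a single gene.

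Genotypes 2, 3 and 4, though not genotype 1, were each set apart from the other Glycine max lines by genes that in part lay together on chromosomes. Genes were taken that passed the edgeR test between 1 Glycine max line and the other 3, lay at least 2-fold from each of them while those 3 lay within 2-fold of one another, and kept their direction in 9 of 9 conditions. Genotype 2 had 43 such genes, with 21 on chromosome 14 and 13 on chromosome 10, in a span that holds E2. Genotype 3 had 59, with 16 each on chromosomes 5 and 19, and the span on chromosome 19 holds Dt1 (Glyma.19G194300), the soybean TERMINAL FLOWER homolog, and E3, with 15 of the 16 genes before E3 and 1 after it. Genotype 4 had 83, of which 60 (72.3%) lay on chromosome 6 in a span that holds E1. In genotypes 2, 3 and 4 a permutation of the chromosome labels gave p = 1e-04, the smallest that 10000 draws can give, and in genotype 1, with 16 genes, it gave p = 0.683. This comparison was chosen after the data were seen.

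**Figure D4:**
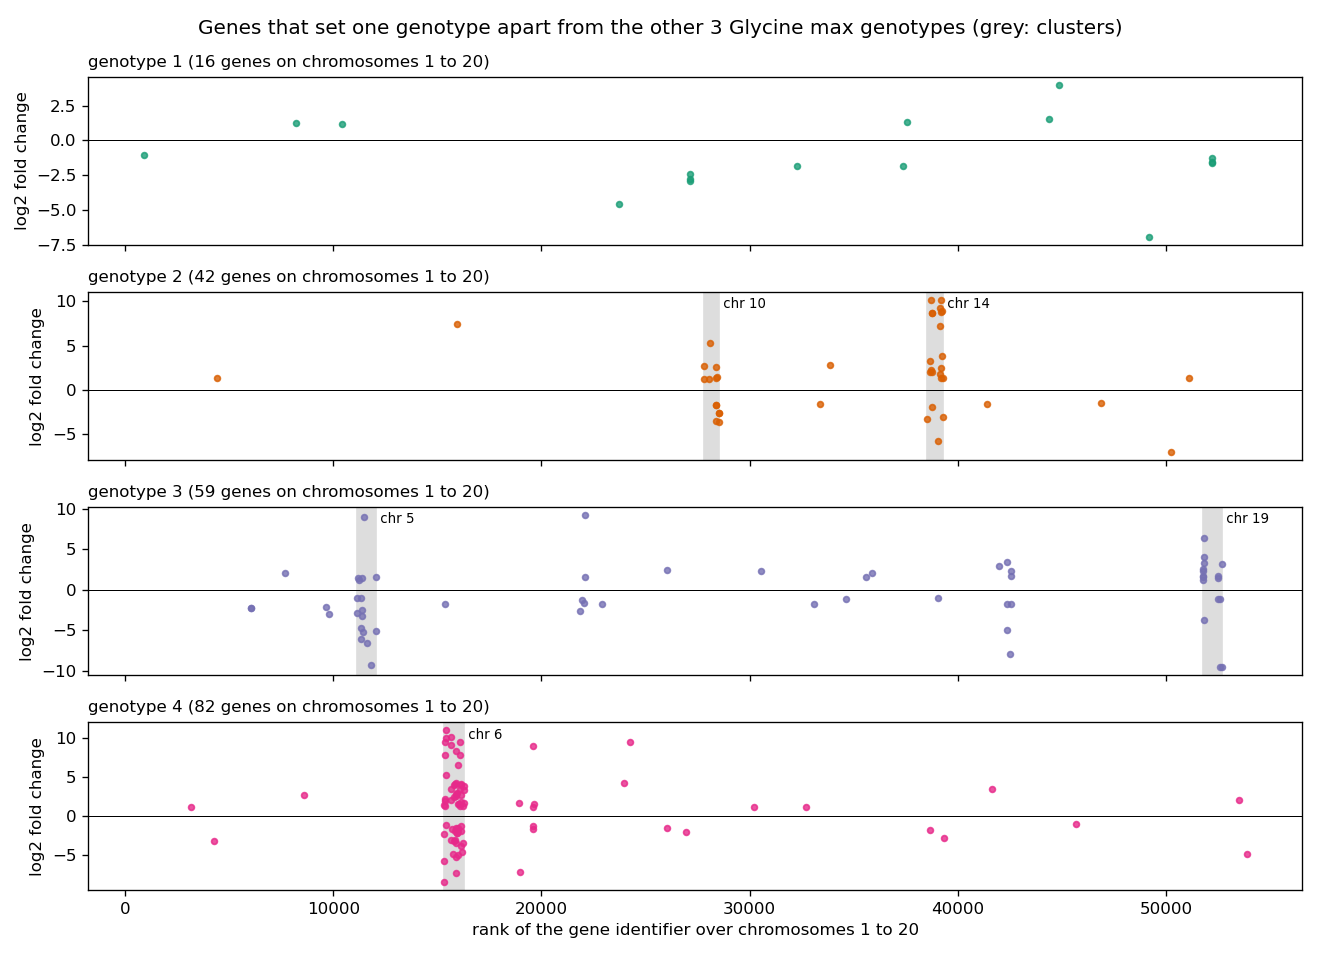
Log2 fold change (vertical axis) of the genes that set each of genotypes 1 to 4 apart from the other 3 Glycine max lines, against the rank of the gene identifier over chromosomes 1 to 20, with 16, 42, 59 and 82 points and clusters shaded grey. Genotype 4 has 60 genes on chromosome 6 and genotype 2 has 21 on chromosome 14.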

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

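The tests for exchanged wells, for chromosome segments and for the E3 region were chosen after the result was seen, and those for read share, depth and relabelled splits were written before.

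Of 810 wells, 11 lay nearest to another genotype than labelled on genes that separate genotypes, and of 540 II wells 4 lay nearest to another time, 12 wells in all. Genotype and time mismatches fell on the same wells more often than chance gives (3 wells, Fisher exact two-sided p = 3.05e-06 over the II wells), which is consistent with wells exchanged or misnamed between sampling and library. A low share of reads counted is argued against, since 1 of the 12 wells lay under 80%, and so is low depth, since 2 of the 12 lay below the lower quartile. At LD, 32 °C and D7, a well of genotype 5 and a well of genotype 2 each lay nearest to the other's genotype. No biological explanation was tested for this pattern.

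Genes that set genotypes 2, 3 and 4 apart lay together on chromosomes, in 5 clusters. A candidate explanation is that chromosome segments of another parent hold a maturity locus, since 3 of the 4 loci E1 to E4 lay inside the 5 spans and spans placed at random gave as many with a permutation p of 0.0019. E3 lay inside through the last gene of its span alone. The spans on chromosome 14 in genotype 2 (21 genes) and on chromosome 5 in genotype 3 (16 genes) held none of the listed flowering genes. For those clusters the explanation therefore has no listed locus. Without the outermost genes at each end of the spans, 1 or more by the size of the cluster, 2 loci were held, with a permutation p of 0.030. Reads lost to sequence variants against the reference would move nearly all genes of a cluster in 1 direction, if the variants lay in the line set apart alone or in the other 3 alone. In all, 65.1% (82 of 126) went with their cluster's majority, which was upward in 4 of the 5 clusters. The share ran from 7 of 13 on chromosome 10 to 17 of 21 on chromosome 14, both in genotype 2. Variants on 1 side alone are thus argued against as the whole cause. Variants on both sides could move genes either way, so they stay open. Whether the segments act on flowering genes such as FT2a was not tested.

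In genotype 3, E3 stood at 48.0% of its mean level in genotypes 1, 2 and 4, and the next gene, Glyma.19G224300, at 0.126% (0.00997 against 7.90 CPM, from 25 counts over the 9 conditions of genotype 3). Lower counts of the whole region are argued against, since 4 flanking genes had a median ratio of 1.03 (0.883 to 1.52). A deletion that reaches from E3 into the next gene stays open, because the level of the next gene is the value that drew attention to it and no other value was tested. A sequence change that stops reads of that gene from aligning was not tested either.

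Differences between groups that passed a test of the difference itself are given here without explanation. The response to SD differed from that at 25 °C in 24009 genes at 16 °C (14362 to 15145 in additive fits with 1 well per cell) and in 30006 at 32 °C, and at 32 °C that of Dt2 differed by 1.25 and that of FT5a by 1.23. The change from D1 to D7 differed between SD and LD in 10775 genes, with -3.31 for E1, which was too low in SD to be tested there, -2.46 for FT5a and -1.20 for COL1b. In an additive limma-trend fit with the title prefix as a term 0 flowering genes passed this test, and in additive fits with 1 well per cell 1 to 2 did, against 11. The response to SD differed among genotypes in 7184 genes. The pattern over II1 to II6 differed between SD and LD in 18150 genes, between 16 and 25 °C in LD in 23976, and between 32 and 25 °C in LD in 24856.

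A single value stood far from the others of its group: LHY1a changed by -0.30 between LD and SD at 25 °C in genotype 5, and by -0.23 to -0.20 in the other genotypes. It was the 1 value marked in 26 groups of 5, and chance marks about 1 in 20 such groups. At D0, a time outside the comparisons, florigen and AP1 homologs had a higher level in SD than in LD: FT2a 24.2 CPM, FT5a 40.2, FT2b 4.93, AP1a 2.04, AP1b 1.03 and AP1c 1.58.

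Labels of the compared condition, time or genotype were exchanged at random among wells alike in the other labels, in 50 splits per result with the real one included, and limma-trend counted genes in each. Genotype 5 was treated likewise on its sums. In every result listed here 1 of the 50 splits, the real one, gave as many genes, the smallest share that 50 splits allow. A random split mixes wells of different labels in 1 cell, which raises the spread within cells and lowers its count. Between conditions a plate or chamber effect would pass the same test. For SD against LD the real split gave 29935 genes and the highest other 7 at 25 °C, 23420 and 833 at 16 °C, and 31943 and 314 at 32 °C. For Sh the counts were 28845 and 9 against LD, and 31121 and 50 against SD. For temperature they were 34671 and 2 (32 against 25 °C, LD), 27454 and 1 (16 against 25 °C, LD), 29576 and 22 (32, SD), and 32600 and 83 (16, SD). The difference of the photoperiod response gave 26298 and 1 at 16 °C and 33018 and 1 at 32 °C. From D1 to D7 they were 13399 and 8788 in LD, 10221 and 5221 in SD, and 11066 and 241 for the difference. Over II1 to II6 they were 30951 and 1608 in LD, 35375 and 3278 in SD, 18469 and 521 for the pattern between SD and LD, 23971 and 1112 at 16 °C and 25328 and 3590 at 32 °C. The response among genotypes gave 7762 and 1, and genotype 5 gave 32880 and 11681.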

How the results depend on the processing

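The removal of wells that did not match their label, the removal of wells under 80% counted, limma-trend with a replicate block and the additive fit for untestable flowering genes were tests chosen after the data were seen. Of 346 counts of genes under alternatives 325 stayed within 1.5 times, of 286 counts at least 2-fold 261, and of 346 flowering counts 323. Of 2258 values of single flowering genes, 1922 kept direction and side of the threshold, 70 were weaker, 262 stronger and 4 reversed. DESeq2 size factors, no filter, removal of the mismatched or low-share wells and leaving out genotype 4 moved none of 57 values each. Where not stated otherwise, the cause was not tested. With genotypes as replicates, SD against LD at 16 °C gave 3593 genes by edgeR and 7191 by DESeq2 (21964 reported), Sh against SD 19394 by edgeR (29219), 16 against 25 °C in LD 16581 by edgeR (26190) and at least 2-fold 1164 and 1168 (733), and 32 against 25 °C in SD at least 2-fold 1440 and 1454 (939). On D1, D3 and D7, SD against LD at 16 °C gave 11555 genes, 16 against 25 °C in LD 17053, 32 against 25 °C in SD at least 2-fold 1836, and 26 flowering genes at 32 °C (17), and E2 between 16 and 25 °C in SD turned from 1.37 to -0.0483. On II1 to II6, at least 2-fold counts were 1830 for Sh against LD (1179) and 1299 for 16 against 25 °C in LD, with 20 flowering genes for 32 against 25 °C in LD (13). By limma-trend, also with the replicate block, at least 2-fold counts were 433 at 16 °C for SD against LD (712), 442 for 16 against 25 °C in LD and 587 for 32 against 25 °C in SD, and flowering genes 21 for 32 against 25 °C in LD, 23 and 20 for the photoperiod response at 16 and 32 °C (12, 13). By limma-trend alone they were 18 for the difference of D7 and D1 (11) and 20 for the response among genotypes (10). An additive limma-trend fit with the title prefix as a term changed test, model and term at once, so these counts do not single out the prefix. At least 2-fold counts were 431, 426 and 592 in the same 3 contrasts, near those of limma-trend alone, and the difference of D7 and D1 gave 1307 genes (10775), 1266 at least 2-fold (3103) and 0 flowering genes. With an estimated correlation the adjusted p of the floral MADS-box genes became 0.155 for SD against LD at 25 °C (3.80e-04), 0.155 at 32 °C (3.80e-04) and 0.0785 for Sh against SD (3.40e-04), and that of the flowering genes 0.262 for SD against LD at 16 °C (0.0161) and 0.262 for D7 against D1 in LD (0.00952). The position of Sh (0.335) became -3.39 with no fold limit, 0.205 with at least 4-fold change, 0.150 with the rising genes alone and 1.36 with the falling genes alone. Without genotype 3 the response among genotypes gave 2928 genes and without genotype 5 2858 (7184), the difference of D7 and D1 gave 7 flowering genes without either, D7 against D1 in LD gave 7 without genotype 2 (12), and D7 against D1 in SD 6391 genes without genotype 1 (9934). Genotype 5 against genotype 2 gave 21953 genes (32935) and 8 flowering genes (19), and against genotype 3 12. FT1a turned to -0.0365 against genotype 1, FT2b to -0.86 against genotype 3 and AP1a to -0.20 against genotype 4. In additive fits with 1 well per cell, counts were 581 to 3339 for the difference of D7 and D1, 523 to 1742 at least 2-fold and 1 to 2 flowering genes. They were 2448 to 3817, 1166 to 1839 and 3 to 3 for D7 against D1 in LD (13256, 2324 and 12), and 471 to 807, 227 to 617 and 0 to 6 in SD (9934, 1525 and 10). They were 10358 to 10967 and 924 to 1087 for SD against LD at 16 °C, 14362 to 15145, 2274 to 2626 and 7 to 9 for the photoperiod response at 16 °C (24009, 1695 and 12), and 939 to 1125 at least 2-fold for 16 against 25 °C in LD. Replicate letters do not pair wells: across genes, which are not independent replicates, same-letter deviations in SD and LD at 25 °C correlated with a median r of 0.008 over 45 strata (-0.464 to 0.458). Not run were the inclusion of libraries with no plate well, and the title prefix as a term for D7 against D1 within LD or SD, which left no residual degrees of freedom. Depth limits genes near the floor, such as the E1 family in SD.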

Other observations

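At D0 and 25 °C, where wells of both day lengths lay on the same plate, florigen genes, which promote flowering, had a higher level in SD than in LD. FT2a stood at 24.2 ± 8.24 CPM in SD and 1.02 ± 1.75 CPM in LD (mean ± standard deviation, n = 5 genotypes), FT5a at 40.2 ± 14.3 and 4.26 ± 4.98 CPM, and FT2b at 4.93 ± 2.82 CPM in SD with 0 counts in LD. AP1a stood at 2.04 ± 2.15 and 0.0678 ± 0.0652 CPM, and the repressors went the other way, with FT1a at 0.0251 ± 0.0345 CPM in SD and 5.00 ± 3.40 CPM in LD, and E1 at 0.0174 ± 0.0203 and 1.32 ± 1.09 CPM. Each of these had the same direction in 5 of 5 genotypes, with a two-sided exact sign permutation p of 0.0625, the smallest possible.

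The I series, sampled in genotype 4 at 25 °C with 2 wells each, was in no comparison. E1 in LD was highest at I5 with 5.49 CPM, against 1.32 CPM at I3, 0.722 CPM at I4 and 0 counts at I6. LHY1a stood at 2783 CPM in LD and 2609.6 CPM in SD at I1, and E2 at 329.7 CPM in LD at I4 and 461 CPM in SD at I3. FT2a was at 34.7 CPM in SD at I1 and 12.0 CPM at I5, and at 3.46 CPM in LD at I3.

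Days D2, D4 and D6 were sampled in genotype 4 in 9 conditions, with 2 wells each. FT2a in SD at 16 °C stood at 3.21 CPM on D1, 20.7 CPM on D2, 22.3 CPM on D3, 35.2 CPM on D4, 27.8 CPM on D6 and 38.7 CPM on D7. Its course differed among conditions. In LD at 16 °C it stood at 0.631 CPM on D1, 13.2 CPM on D6 and 1.69 CPM on D7. In LD at 32 °C it went from 3.92 CPM on D1, in wells with 37.7 and 56.9% of reads counted, to 0.212 CPM on D7. The D1 well with 56.9% lay nearest to genotype 5, by 53.3% of the genes that separate genotypes 4 and 5.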
